A study of Mus musculus with 12 samples.

How the data were processed

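RNA was measured by sequencing in 12 mouse brain libraries, 4 in each of 3 groups. Per the labels' protocols, each library came from a cross-section of brain that held hippocampus and cortex, and was made from total RNA with a kit that does not mark the strand. Per the series' design text, reads were paired-end, 101 bases long, and came from a HiSeq 4000. Per the submitters' processing notes, reads were handled with bcl2fastq, TopHat and featureCounts of the Subread package on the mm10 build. The versions of these tools and the annotation release were not given in the sources used here.

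The deposited table held 43346 genes with their position, a length and, for each library, a count and an RPKM value. Per the file headers, the first kind of value is a gene count made by the authors, and the values were whole numbers with no scaling. Per the file headers, the second kind is an RPKM value made by the authors. Recomputing it from the count and the deposited length showed that its total per library was larger than the sum of the counts, which came to 79.9 to 85.4% of that total. RPKM values were used for that check only. No column of the table was left without a known meaning. Of the gene identifiers, 42462 occur in the GENCODE vM21 annotation, and symbols and mm10 positions were taken from the deposited table.

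Depth ranged from 70548781 to 99449665 counts per library. One CPM, a share of counts scaled to the library's depth, stood for 70.55 to 99.45 counts. No pair of libraries within a group had counts close enough to be copies of each other, with a chi-square per gene of at least 14.7 over genes with 20 or more counts in the pair. The 13 protein genes of the mitochondrial genome were listed at 0 in all 12 libraries, so that genome was not analysed here.

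Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups as input, which left 22553. Library factors came from TMM, and a quasi-likelihood fit used all 12 libraries with the group as the only term. Each comparison was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from this edgeR test unless another tool is named. Group values are normalised CPM, given as mean ± SD of 4 libraries, and fold changes are on the log2 scale with edgeR's prior count and a standard error taken from the F statistic. Where a group held 3 or fewer reads of a gene, the ratio of reads is given with its 95% counting interval, which covers counting error only.

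The groups, comparisons, gene lists, tests and rule for naming genes were fixed before the data were examined. In each comparison, genes were eligible for naming if they were called, had a mean of at least 1 CPM over the 12 libraries and had no overlap between the 4 and 4 values. Of these, the 6 with the largest change and a further 4 with the smallest p were named in each direction. Where fewer than 10 genes were eligible, all were named, followed by the genes of smallest unadjusted p up to 10. Gene models without a proper name and antigen receptor genes were counted but not named, with exceptions that are stated where they occur. Up to 4 members of a described gene list, taken by smallest p, were named as well, and Gfap, C4b, Serpina3n, Nnt, App, Xist, Ddx3y, Ppargc1a and Ttr were always given, while a further gene of that rule is not reported here.

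In all, 43 gene lists were written from textbook knowledge, covering mitochondrial complexes, metabolism, stress responses, cell types, brain regions, blood, sex and strain. The 40 lists suited to a set test, those with at least 5 measured genes and not concerned with sex or strain, were tested with camera of limma 3.58.1, which asks whether a list's genes moved more than other genes. The preset correlation between genes was 0.01, and p-values were adjusted over the 40 lists. Each test was repeated with a correlation estimated from the data, and with fry, which does not compare a list with other genes. In no called list did the sign of the median differ from that of the test. Members of a list were counted after adjustment over all genes and after adjustment over the list alone.

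The gene test and the list test were run on simulated counts. These took each gene's mean over all 12 libraries and the depth of each library, with changes set in the treated old group only. Changed genes were drawn from those above a minimum mean count, so the shares found hold for such genes. With 22259 genes tested, edgeR found 59% of the genes changed 1.5-fold and 72% of those changed 2-fold, and 2.24% of its calls were false. DESeq2 found 66% and 78%, with 23% false calls. Limma voom found 58% and 73%, with 2.96% false calls. Camera found 5 of 5 lists moved 1.25-fold and made 0 false calls. The simulated genes varied independently, however, so this does not test the preset correlation. In the regroupings of real libraries described below, the same test called a median of 15, 14.5 and 17 lists in the 3 comparisons.

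A pair of comparisons that share a group are not independent. The share of genes called between Old and Young that moved in the opposite direction under CP2, and the covariance of both sets of fold changes, were therefore set beside 100 simulated data sets. They were also set beside the 6 ways to divide the 4 Old libraries between both comparisons. As alternatives, each count was recomputed with DESeq2 1.42.0, with limma voom with and without library weights, with RLE and upper quartile factors, with no filter and with a stricter filter on low counts, with only the groups compared, with other thresholds, with 1 surrogate variable from sva 3.50.0, and without each library in turn. After seeing the data, 2 alternatives were added, which were a fit with the choroid plexus list as a covariate and a fit without the 4 libraries lowest in choroid plexus transcripts. The latter left out Old 7, Old 9, Old_CP2 11 and Old_CP2 15, so each old group kept 2 of its 4 libraries. Calls that it ended or gained can come from the smaller groups alone. The labels gave no sex, cage, batch or pairing, so none was a term in a fit. To test explanations, further lists of midbrain and hindbrain, erythroid, platelet, and neutrophil and monocyte genes were written and set beside 10000 random lists matched on expression. Each comparison was also rerun for all 35 ways to split its 8 libraries into 4 and 4.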

Results

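Brain RNA was sequenced from 3 groups of mice labelled wild type, with 4 libraries in each. The design text of the series instead describes treated and untreated mice of a transgenic line beside non-transgenic ones. All sample titles begin with NTG, which can be read as non-transgenic and goes with the labels. The conflict between the design text and the labels could not be settled further. Young mice were 3 months old, carried the strain label C57BL/6 and were untreated. Old mice were 23 months old, carried the strain label C57BL/6;SJL-Tg and drank water with 0.1% polyethylene glycol (PEG), the vehicle, from 9 months of age. Old_CP2 mice had the same age and strain label and received CP2, an inhibitor of complex I of the mitochondrial respiratory chain, at 25 mg per kg per day in the same vehicle and from the same age. Depth was 77469073 to 91549618 counts in Young, 70548781 to 94741585 in Old and 78021395 to 99449665 in Old_CP2. Over log2 CPM of the 22553 tested genes, libraries of 1 group correlated at 0.986 to 0.992 and libraries of different groups at 0.977 to 0.99. The first component of a principal component analysis held 28.3% of the variance and the second 12.4%. The female transcript Xist was abundant in every group, at 704 CPM in Young, 1059 CPM in Old and 976 CPM in Old_CP2, while the Y-linked Ddx3y had at most 4 reads per group. The p-values measure spread between libraries only, and the labels do not state that each library is a separate animal.

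The comparison of Old with Young asks how the brain differed between 23 and 3 months. Among the genes eligible for naming, with a mean of at least 1 CPM and no overlap, those with the largest increases included transcription factors and transporters of midbrain and hindbrain neurons. Pou4f2 (ENSMUSG00000031688, chromosome 8, 78433010 to 78436645, mm10), a POU-domain factor of the dorsal midbrain and retina, had 605 reads in Old and 1 in Young, a ratio of 609 (95% counting interval 109 to 24107; adjusted p = 1.85e-05). Pax7, a factor of the dorsal midbrain, was at 4.00 ± 0.116 CPM in Old and 0.174 ± 0.107 in Young (n = 4 each; log2 fold change 4.49 ± 0.35 SE, edgeR adjusted p = 4.39e-05). Tfap2b rose by 4.24 on the log2 scale to 7.69 ± 3.43 CPM, and Tal1, a factor of midbrain inhibitory neurons, rose by 1.86 to 9.22 ± 0.624 CPM. The serotonin transporter Slc6a4 rose from 0.107 ± 0.0697 to 3.94 ± 2.46 CPM, the glycine transporter Slc6a5 from 0.271 ± 0.0572 to 10.1 ± 15.4 CPM and Cnpy1, a gene of the midbrain-hindbrain boundary, from 0.16 ± 0.145 to 7.54 ± 12.7 CPM. The Cnpy1 and Slc6a5 means rested on Old 7, at 26.6 and 33.2 CPM. Fermt1, a kindlin of integrin adhesion, rose by 2.32, Xist by 0.59 and Efr3a, a membrane anchor of a lipid kinase, by 0.52 on the log2 scale, with adjusted p of at most 0.000343 for all 3. Of the genes that fell by most, Adora2a, the adenosine receptor of striatal neurons, went from 15.2 ± 7.59 to 2.92 ± 1.88 CPM (log2 fold change -2.38 ± 0.507, adjusted p = 0.0157). Lower too were the hypothalamic peptide genes Hcrt (-4.92) and Gal (-2.37) and Isl1 (-3.10), a factor of striatal and hypothalamic neurons. So were the ubiquitin ligase gene Sh3rf2 (-2.19) and the ependymal Tmem212 (-1.96 on the log2 scale). Smaller and tighter decreases were found in Gnb4, a G protein subunit (-0.81, adjusted p = 4.09e-05), Mmp15, a membrane metalloproteinase (-0.70), Tmem163, a zinc transporter (-0.57), and Sh3gl3, an endophilin of synaptic vesicle uptake (-0.34).

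Gfap, the intermediate filament of astrocytes, was at 374 ± 80.4 CPM in Old and 214 ± 30.3 in Young (0.81 ± 0.133, adjusted p = 0.00491), and the complement gene C4b was at 94.9 ± 34.2 and 21 ± 4.13 CPM (2.18 ± 0.243, adjusted p = 0.000738), and both rose. In the list of disease-associated microglia, 14 of 24 genes rose and 0 fell over all genes, and 20 rose and 1 fell adjusted over the list alone (median 0.56 on the log2 scale). Itgax, a microglial integrin, rose by 2.75, the lysozyme gene Lyz2 by 1.61, the cathepsin gene Ctsz by 0.42 and the growth factor gene Csf1 by 0.30. This list held its call with an estimated correlation (limma camera adjusted p = 0.0292). So did neurogenesis (median -0.295, adjusted p = 0.0167), where 7 of 18 genes fell over all genes, and 9 fell and 1 rose adjusted over the list alone. Among them were Igfbpl1, a gene of newborn neurons (-2.38), the cell division genes Mki67 (-0.97) and Top2a (-1.58), and the neuronal tubulin Tubb3 (-0.25).

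A further 10 lists were called upward with the preset correlation only. Over all genes, 9 of 27 complement and antigen presentation genes rose (adjusted p = 0.121 with an estimated correlation). So did 4 of 20 homeostatic microglia genes (adjusted p = 0.151 with an estimated correlation), 5 of 22 cytokine genes (adjusted p = 0.107 with an estimated correlation) and 4 of 29 interferon-stimulated genes (adjusted p = 0.361 with an estimated correlation). Adjusted over the list alone, 14, 12, 6 and 11 of these rose and 0 fell. Examples are C1qa (0.58), Casp1 (1.37) and Ifit3 (0.79 on the log2 scale). Increases were also found for 6 of 15 astrocyte marker genes, 13 adjusted over the list alone (adjusted p = 0.0596 with an estimated correlation), and 6 of 31 reactive astrocyte genes, 11 adjusted over the list alone (adjusted p = 0.344 with an estimated correlation), among them the gap junction gene Gjb6 (0.32) and Aspg (1.02). In the matrix and collagen list 6 of 25 genes rose, and adjusted over the list alone 6 rose and 3 fell (adjusted p = 0.384 with an estimated correlation). In the meningeal fibroblast list 5 of 16 rose and 1 fell, and adjusted over the list alone 10 rose and 2 fell (adjusted p = 0.347 with an estimated correlation), with the matrix gene Dcn at 47.8 CPM in Old and 18.9 in Young. In autophagy and lysosome 4 of 31 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.347 with an estimated correlation). Among 19 lymphocyte genes 3 rose and 1 fell, and adjusted over the list alone 6 rose and 3 fell (adjusted p = 0.469 with an estimated correlation), with Cd8a higher by 3.09 and Cd4 lower (-2.03). Of these 10, autophagy and lysosome was not called without Young 1 (adjusted p = 0.0849), Old 8 (0.0505) or Old 10 (0.0516), lymphocytes without Young 1 (0.112) or Old 10 (0.103), and matrix without Young 5 (0.0506).

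A further 7 lists were called downward with the preset correlation only. In the striatum list 12 of 15 genes fell, 14 adjusted over the list alone (median -0.914, adjusted p = 0.107 with an estimated correlation), with the enkephalin precursor Penk at 35.3 CPM in Old and 87.9 in Young and the dopamine signalling gene Ppp1r1b at 67 and 121 CPM. In the thalamus and habenula list 8 of 16 genes fell, and adjusted over the list alone 12 fell and 1 rose (median -0.61, adjusted p = 0.256 with an estimated correlation). Examples are the transcription factor Lef1 (-0.91) and the actin-binding Synpo2 (-1.60). In the hypothalamus and amygdala list 4 of 16 fell, 10 adjusted over the list alone (median -2.01, adjusted p = 0.347 with an estimated correlation), among them the oxytocin gene Oxt, at 0.191 CPM in Old and 7.73 in Young. Of 19 choroid plexus and ependyma genes 1 fell, 1 adjusted over the list alone (median -1.35, adjusted p = 0.362 with an estimated correlation). The choroid plexus gene Ttr was at 1408 ± 348 CPM in Young and 421 ± 417 in Old, where it ran from 6.81 to 861 CPM (adjusted p = 0.46). The others were precursors of oligodendrocytes (2 of 14 fell, 4 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation), glutamatergic neurons (1 of 19 rose and 1 fell, and adjusted over the list alone 1 rose and 4 fell, adjusted p = 0.575 with an estimated correlation) and synapse (2 of 30 fell, 2 adjusted over the list alone, adjusted p = 0.667 with an estimated correlation). The neuron and synapse lists were not called without Old 7 (adjusted p = 0.0693 and 0.253).

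Of 36 nuclear genes for complex I, the target of CP2, 0 were called by edgeR and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 (median -0.06, limma camera adjusted p = 0.142), although the list was called without Young 3 (0.00516) and without Old 7 (0.0092). Its median ran from -0.0914 to 0.000321 without single libraries. Ppargc1a, a regulator of mitochondrial biogenesis, was at 60.3 ± 1.09 CPM in Old and 52.9 ± 2.82 in Young (0.19, adjusted p = 0.0474). Serpina3n (adjusted p = 0.228), Nnt (0.903) and App (0.684) did not pass.

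In all, 1511 genes were called, 893 higher and 618 lower in Old, of which 305 changed more than 2-fold, and 4835 had an unadjusted p under 0.05 against 1128 by chance. Values of the 4 and 4 libraries did not overlap for 13.3% of genes, where chance gives 2.86%. Age, strain label and vehicle all differed between these groups. The count fell to 855 without Young 4, 971 without Young 5, 934 without Old 7 and 952 without Old 9, and to 247 with the choroid plexus list as a covariate. Leaving out 1 library ended the calls of Cnpy1 (Young 1, Young 4, Young 5 or Old 7; adjusted p 0.0562 to 0.0738), Slc6a5 (Young 1, Young 4 or Young 5; 0.0536 to 0.0586), Hcrt (any but Young 5; 0.0698 to 0.101), Isl1 (any but Young 5 and Old 10; 0.055 to 0.0762), Sh3rf2 (Young 3, Old 7 or Old 9; 0.0523 to 0.0553), Tmem212 (Old 9; 0.0506) and Ppargc1a (any but Young 1; 0.0607 to 0.106), and the call of Ppargc1a also ended with no filter on low counts (0.0579). The choroid plexus covariate, chosen after seeing the data, ended those 7 calls and the calls of Adora2a (adjusted p = 0.116), Gal (0.186) and Slc6a4 (0.0918), with an adjusted p up to 0.439. All Young libraries scored above all old libraries on that list, and Tmem212 is a member of it. Such losses are thus in part built in. Without the 4 libraries lowest in choroid plexus transcripts the calls of Adora2a (0.0768), Gal (0.108), Hcrt (0.118), Isl1 (0.0768), Tmem212 (0.071) and Ppargc1a (0.119) ended. Their log2 fold changes were then -1.8, -2.14, -4.83, -2.48, -1.37 and 0.204, in the same order.

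**Figure D1:**
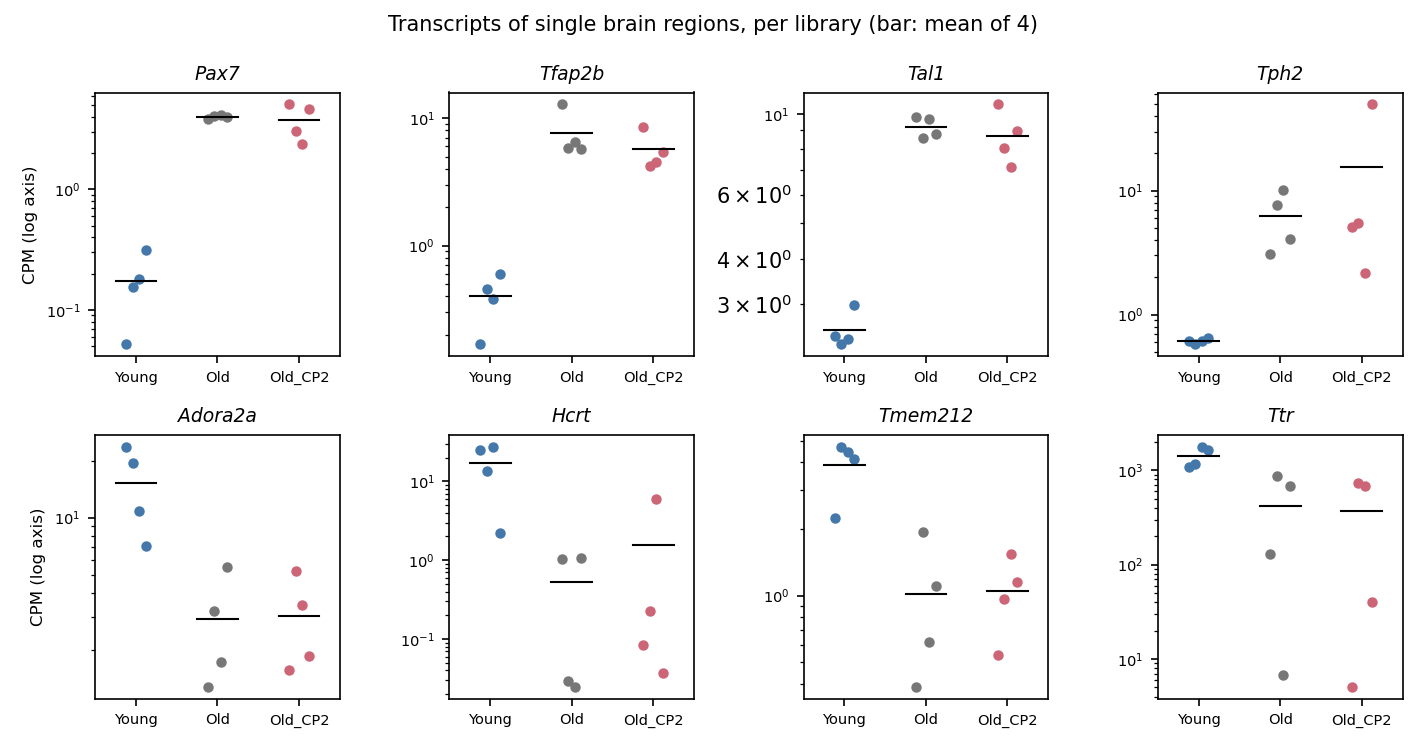
Normalised CPM on a log axis of 8 transcripts of single brain regions in the 12 libraries, with 1 point per library and a bar at the mean of 4. Pax7 lies between 0.0518 and 0.312 CPM in Young and between 3.85 and 4.11 CPM in Old, while Ttr spreads from 6.81 to 861 CPM within Old.

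The comparison of Old_CP2 with Old addresses the treatment at the same age and strain label. Both alpha globin transcripts were higher in the treated mice. Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298), an alpha globin of red blood cells, was at 56.8 ± 19.2 CPM in Old_CP2 and 11.9 ± 3.58 in Old (n = 4 each; log2 fold change 2.25 ± 0.268 SE, edgeR adjusted p = 0.00526). Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) was at 72.8 ± 27.6 and 17.7 ± 5.14 CPM (2.04 ± 0.255, adjusted p = 0.00653). Frem2 (ENSMUSG00000037016, chromosome 3, 53513939 to 53657355), a basement membrane protein, fell from 13.2 ± 1.05 to 4.20 ± 0.323 CPM (-1.66 ± 0.101, adjusted p = 4.04e-06). Mypn, a protein of muscle sarcomeres, rose by 1.10 ± 0.167 to 4.20 ± 0.857 CPM (adjusted p = 0.0404), and the RNA-binding protein gene Rbm46 rose by 1.84 ± 0.283 to 1.39 ± 0.246 CPM (adjusted p = 0.0411). The aldehyde oxidase gene Aox4 went from 2.91 ± 0.67 to 1.15 ± 0.0843 CPM (-1.34 ± 0.2, adjusted p = 0.0382). The other 4 called genes were gene models without a proper name, given here after their values were seen. Gm14513 (X chromosome, 11684002 to 11684124) had 1213 reads in Old_CP2, 16 in Old and 10 in Young, and Gm14131 (chromosome 2) had 185, 9 and 10. 1500004A13Rik and 5830417I10Rik, which overlap on chromosome 3 and whose reads cannot be told apart by strand, had log2 fold changes of -0.84 and -0.67. Next by unadjusted p, and not called, were Alas2, the heme synthesis enzyme of red blood cells (9.72 ± 2.57 and 3.42 ± 1.07 CPM, adjusted p = 0.0588), the DNA repair gene Tdg (0.0649), the collagen hydroxylase gene P4ha3 (0.0796) and Obp2b (0.0981), which had 7 reads in Old_CP2 and 49 in Old. Alas2 and Tdg were called without Old_CP2 15 (0.0491 and 0.0411).

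**Figure D2:**
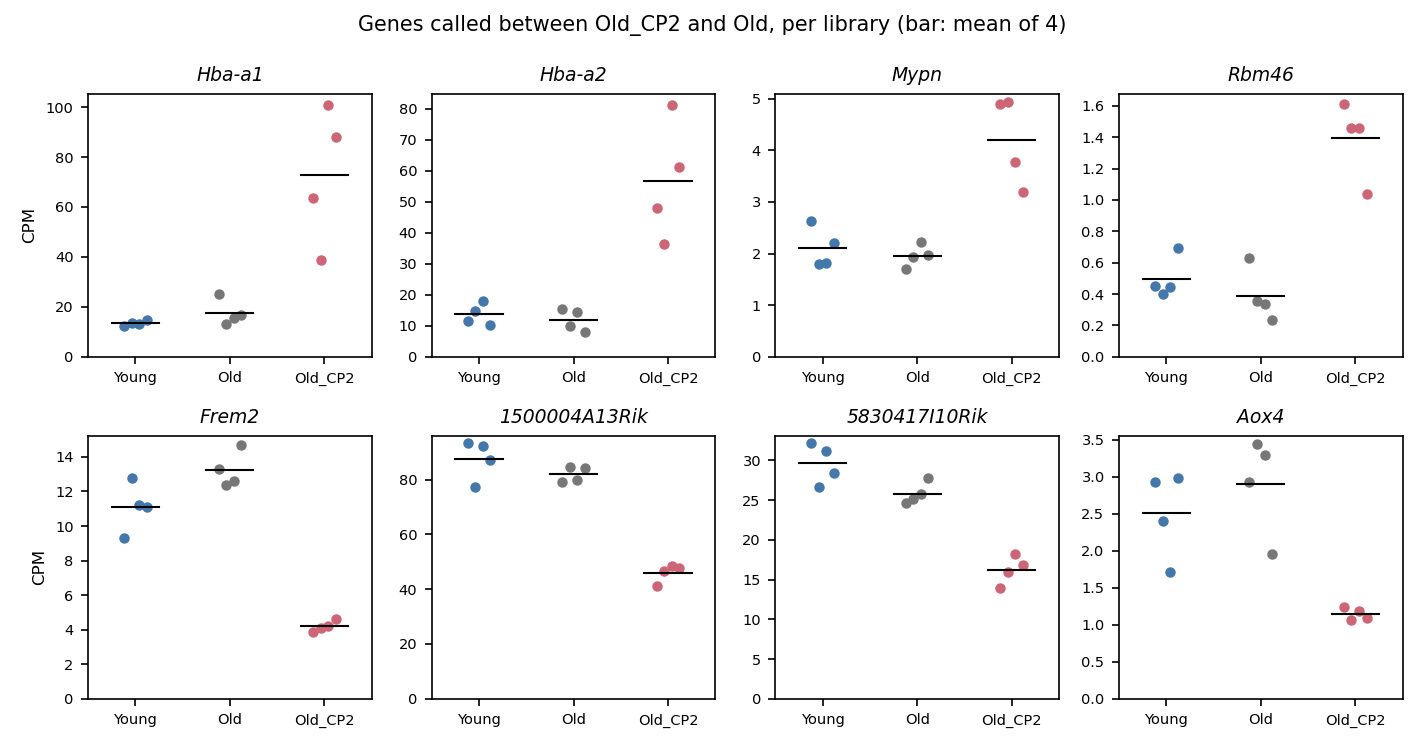
Normalised CPM of 8 of the genes called between Old_CP2 and Old in the 12 libraries, with 1 point per library and a bar at the mean of 4. Frem2 lies between 3.86 and 4.64 CPM in Old_CP2 and between 12.4 and 14.7 CPM in Old.

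Of the fixed lists, 2 held their call with an estimated correlation. Among 10 erythrocyte genes 2 rose over all genes, 7 adjusted over the list alone and 0 fell (median 1.42 on the log2 scale, adjusted p = 0.00532 with an estimated correlation), and the beta globin Hbb-bs was at 134 CPM in Old_CP2 and 45.2 in Old. Among 15 astrocyte marker genes edgeR called 0 over all genes, with 8 at an unadjusted p under 0.05, and 8 fell and 0 rose adjusted over the list alone (median -0.18, adjusted p = 0.0415 with an estimated correlation). Acsbg1, a fatty acid activating enzyme, was at 150.3 CPM in Old_CP2 and 184 in Old, the growth factor receptor gene Fgfr3 at 140.2 and 166 CPM, and the gap junction gene Gja1 at 209.6 and 244 CPM. Gfap was at 376 ± 33 and 374 ± 80.4 CPM (adjusted p = 0.996) and C4b at 96.3 ± 18.9 and 94.9 ± 34.2 CPM (adjusted p = 0.993).

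The remaining 17 lists called with the preset correlation had 0 members called over all genes by edgeR, with 0 to 8 each at an unadjusted p under 0.05. Pericyte and smooth muscle genes were higher by a median of 0.40, 5 of 15 adjusted over the list alone (adjusted p = 0.224 with an estimated correlation), with Rgs5, a pericyte regulator of G protein signalling, at 83.3 CPM in Old_CP2 and 58.5 in Old. Circadian clock genes were higher by a median of 0.11, 6 of 18 adjusted over the list alone (adjusted p = 0.438 with an estimated correlation), with the clock gene Per2 at 37.9 and 30.3 CPM. Medians were higher too for immediate early (0.45), interferon-stimulated (0.27), complement and antigen presentation (0.28) and reactive astrocyte (0.11) genes, with 0 called adjusted over the list alone (each adjusted p = 0.598 with an estimated correlation). The class II genes H2-Aa and H2-Eb1 were at 6.74 ± 6.08 and 5.53 ± 4.40 CPM in Old_CP2, with 15.4 and 11.4 CPM in Old_CP2 11 and 6.41 and 6.42 CPM in Old_CP2 15, against means of 2.25 and 1.62 in Old. Medians of these called lists moved by over 1.5 times without 1 library. The complement median was 0.06 without Old_CP2 11. Without the 4 libraries lowest in choroid plexus transcripts it was -0.04, and the list was not called (limma camera adjusted p = 0.794). The interferon median was 0.16 without Old_CP2 11, and the immediate early median 0.26 without Old 7 and 0.28 without Old_CP2 11. The pericyte median was 0.26 without Old_CP2 15, the circadian median 0.06 without Old 7 and 0.06 without Old_CP2 12, and the reactive astrocyte median 0.18 without Old 7. Lists called upward with an estimated-correlation adjusted p between 0.587 and 0.856 were lymphocytes (0.40), endothelium (0.14), disease-associated microglia (0.06), glycolysis (0.06), glucocorticoid response (0.07), glutamatergic neurons (0.08) and synapse (0.05 on the log2 scale), with 1 lymphocyte gene higher and 1 endothelial gene in each direction adjusted over the list alone. Complex I (median -0.05, adjusted p = 0.864 with an estimated correlation), complexes II to V (-0.07, adjusted p = 0.783 with an estimated correlation), fatty acid oxidation (-0.07, adjusted p = 0.602 with an estimated correlation) and myelin (-0.12, adjusted p = 0.767 with an estimated correlation) were called downward, with 0 members adjusted over the list alone. Leaving out 1 library ended the calls of 12 of these lists (adjusted p 0.0501 to 0.818), which were all those named in the last pair of sentences and the reactive astrocytes, and each of the 8 libraries ended at least 1 of them. For complex I these were Old 7 (0.439), Old 8 (0.0604), Old_CP2 12 (0.489) and Old_CP2 13 (0.0948), and its median ran from -0.13 without Old_CP2 15 and -0.10 without Old 10 to -0.02 without Old_CP2 12. Medians of the others moved by over 1.5 times without Old 7, Old 8, Old 9, Old_CP2 11, Old_CP2 12 or Old_CP2 15 (-0.19 to 0.65), except for fatty acid oxidation. Without Old 7 the test direction reversed for glutamatergic neurons and synapse, without a call (limma camera adjusted p = 0.786 and 0.818). Lists not called otherwise gained calls without 1 library. Choroid plexus was called downward without Old 7, Old 9, Old_CP2 12 or Old_CP2 13 (limma camera adjusted p 0.000112 to 0.037). So were ribosomal proteins (lowest 3.09e-08, without Old_CP2 15), and hypothalamus was called upward (lowest 0.000759, without Old 10). Striatum, thalamus, hippocampal fields, cytokines and senescence gained calls too.

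App (adjusted p = 0.822), Nnt (0.905), Serpina3n (0.83), Xist (0.784), Ppargc1a (0.929) and Ttr (0.988) did not pass. In all 10 genes were called, 6 higher and 4 lower in Old_CP2, and 1422 had an unadjusted p under 0.05 against 1128 by chance. Values did not overlap for 3.44% of genes, where chance gives 2.86%. The count was 6 without Old 9 and 38 without Old_CP2 15, and DESeq2 called 108 genes, which held all 10, in a test that gave 23% false calls on simulated counts. Leaving out 1 library ended the calls of Hba-a1 (Old 9; adjusted p = 0.0572), Mypn (any but Old_CP2 15; 0.0946 to 0.165), Rbm46 (any but Old 7 and Old_CP2 15; 0.0889 to 0.214) and Aox4 (any but Old 10 and Old_CP2 15; 0.0952 to 0.162). With only the 2 groups compared in the fit, the calls of Hba-a1 (0.0515), Mypn (0.0515) and Rbm46 (0.103) ended, and upper quartile factors ended that of Rbm46 (0.0501). Alas2 (0.0166) and Tdg (0.0284) were called with no filter on low counts, and both were called by DESeq2, as were P4ha3 (3.63e-05) and Obp2b (0.0159). The choroid plexus covariate ended the calls of Mypn and Rbm46 (0.0611 each), with log2 fold changes of 1.09 and 1.84, about as in the main fit. Leaving out the 4 libraries lowest in choroid plexus transcripts, which left 2 against 2, ended those of Hba-a1 (0.0651), Mypn (0.14) and Aox4 (0.376). Their log2 fold changes were then 2.21, 1.16 and -1.25.

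The comparison of Old_CP2 with Young asks which differences from the young brain were present under treatment. Pou4f2 had 699 reads in Old_CP2 and 1 in Young, a ratio of 639 (95% counting interval 114 to 25267; adjusted p = 1.03e-05). Pax7 rose by 4.41 ± 0.349 on the log2 scale to 3.80 ± 1.27 CPM (n = 4, edgeR adjusted p = 3.02e-05), Tfap2b by 3.80, Fermt1 by 2.91, Tal1 by 1.77, Efr3a by 0.54 and Rspo2, a Wnt signalling agonist, by 1.13. The serotonin neuron genes Slc6a4 and Tph2 were at 9.06 ± 12.8 and 15.6 ± 22.7 CPM, means that rested on Old_CP2 15 at 28.1 and 49.6 CPM, against 0.107 and 0.611 CPM in Young, and Slc6a5 rose by 4.40. Frem2 fell by 1.40 ± 0.101 on the log2 scale (adjusted p = 1.03e-05). Decreases were also found in Adora2a (-2.32), Tmem212 (-1.89), the Wnt ligand gene Wnt9b (-1.87), Sh3rf2 (-1.81), the adrenergic receptor gene Adra2b (-1.80) and the thalamic kinase gene Prkcd (-1.73). Mmp15 (-0.84), the corepressor gene Hr (-0.79) and the formin gene Inf2 (-0.72) had adjusted p of at most 0.0007. Gfap (0.81, adjusted p = 0.00361), C4b (2.20, adjusted p = 0.000472), Serpina3n (0.94, adjusted p = 0.038), Xist (0.47, adjusted p = 0.000503) and Ppargc1a (0.22, adjusted p = 0.0216) rose. Nnt (adjusted p = 0.785), App (0.624) and Ttr (0.381) did not pass.

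With an estimated correlation 5 lists held. Over all genes 17 of 24 disease-associated microglia genes rose, and adjusted over the list alone 20 rose and 1 fell (adjusted p = 0.0159 with an estimated correlation), with Itgax higher by 3.73. Complement and antigen presentation (20 of 27 rose, 24 adjusted over the list alone), cytokines (7 of 22 rose, 11 adjusted over the list alone) and erythrocytes (7 of 10 rose, and adjusted over the list alone 7 rose and 2 fell) each had an adjusted p of 0.0419 with an estimated correlation. Among them were the peptide transporter gene Tap2 (0.53) and Hba-a1 (2.44). In neurogenesis 5 of 18 genes fell, 10 adjusted over the list alone (adjusted p = 0.0159 with an estimated correlation), with Igfbpl1 at -2.41 and Mki67 at -0.99. Striatum (9 of 15 fell, 13 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation) and thalamus (9 of 16 fell, and adjusted over the list alone 12 fell and 1 rose, adjusted p = 0.16 with an estimated correlation) were lower with the preset correlation. Of the 17 other lists called with the preset correlation, 11 were higher and 6 lower (adjusted p 0.101 to 0.675 with an estimated correlation). Among them 13 of 29 interferon-stimulated genes rose, 23 adjusted over the list alone, with Oasl2 higher by 1.29. In reactive astrocytes 12 of 31 rose, 16 adjusted over the list alone, with the cytokine receptor gene Osmr higher by 0.73. Calls ended without 1 library (adjusted p 0.0519 to 0.355) for complex I (Young 5), complexes II to V (Young 5, Old_CP2 12 or Old_CP2 13) and matrix (Young 5 or Old_CP2 15). They also ended for glycolysis (Young 3, Old_CP2 11 or Old_CP2 12), myelin (Young 5, Old_CP2 11 or Old_CP2 13) and pericytes (Young 5 or Old_CP2 15).

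Both old groups shared 621 genes called higher and 350 called lower than in Young, where 41.4 and 18.1 would be shared if the calls were independent. Because both comparisons use the same Young libraries, these were divided between them, which gave 101 to 165 shared increases and 30 to 62 shared decreases, with at most 8.52 by independence. Of the 1511 genes called between Old and Young, 994 or 65.8% had a fold change of opposite sign between Old_CP2 and Old. Simulated counts in which CP2 changed nothing gave 64 to 69.1%, and dividing the Old libraries between both comparisons gave 35.7 to 55.6%. The covariance of both sets of fold changes across genes, which are not independent replicates, was -0.0442. It was -0.0407 to -0.0272 in the simulated counts in which CP2 changed nothing, -0.0376 to -0.0301 in simulated counts with no effect, and -0.0206 to 0.0526 with the Old libraries divided. The share thus lay within the simulated range, but that simulation called 2482 to 2742 genes between Old and Young against 1511 in the data, so its share was taken over a larger set of genes. The covariance was below both simulated ranges but took either sign when the Old libraries were divided. Without Old_CP2 13 the covariance was -0.031, inside both. In both simulations genes varied independently, so the ranges can be too narrow for genes that vary together. Neither the share nor the covariance therefore decides whether CP2 moved genes toward their level in Young. The share was 73% without Old 8, 74.7% without Old 10 and 55.3% without Old_CP2 13, and the covariance -0.0698 without Old 8, -0.0647 without Old 9, -0.0867 without Old 10 and -0.0648 without Old_CP2 15.

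**Figure D3:**
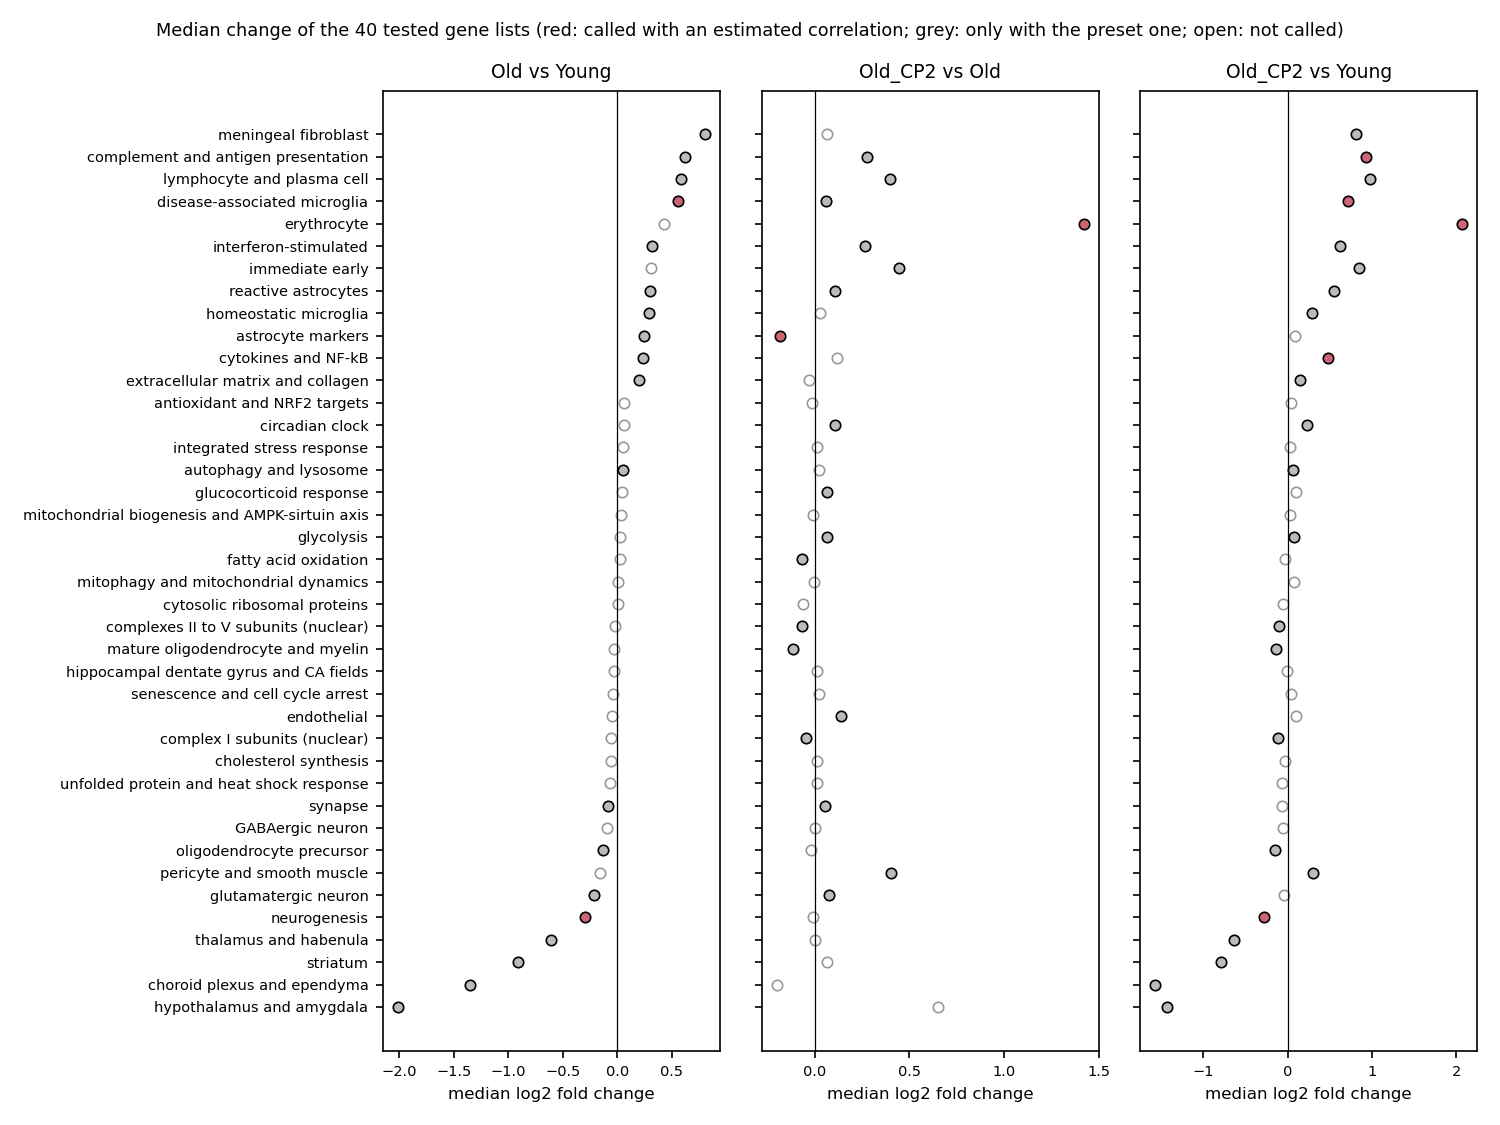
Median log2 fold change of the 40 tested gene lists in the 3 comparisons, with red points for lists called with an estimated correlation, grey points for lists called with the preset correlation only and open points for lists not called. The erythrocyte list lies at 1.42 between Old_CP2 and Old, and the hypothalamus list at -2.01 between Old and Young.

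In all 1707 genes were called, 1045 higher and 662 lower in Old_CP2 than in Young, of which 425 changed more than 2-fold. Values did not overlap for 15.5% of genes, where chance gives 2.86%. The count was 1050 without Young 1, 1036 without Young 4, 827 without Old_CP2 11 and 1043 without Old_CP2 12, and 301 with the choroid plexus list as a covariate. Leaving out 1 library ended the calls of Slc6a5 (any but Old_CP2 12 and Old_CP2 13; adjusted p 0.0645 to 0.0885), Prkcd (any but Young 3 and Old_CP2 13; 0.0664 to 0.113), Serpina3n (any but Young 4 and Old_CP2 15; 0.0797 to 0.101), Sh3rf2 (Young 1, Young 3, Young 4, Old_CP2 11 or Old_CP2 15; 0.0638 to 0.0977), Tmem212 (Old_CP2 11 or Old_CP2 12; 0.051 to 0.0561), Adora2a (Old_CP2 11; 0.0505), Wnt9b (Young 1; 0.0521) and Ppargc1a (Young 4 or Old_CP2 11; 0.0532 to 0.0654). The choroid plexus covariate ended these 8 calls and those of Tph2 (0.148), Slc6a4 (0.0734) and Adra2b (0.0825), with an adjusted p up to 0.438. The limit given above for this covariate holds here too. Without the 4 libraries lowest in choroid plexus transcripts the calls of Adora2a (0.0638), Prkcd (0.103), Sh3rf2 (0.104) and Ppargc1a (0.0963) ended, and Ttr was called (0.0311).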

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

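Every test of neighbouring or crowded genes below, and the look at neutrophil and monocyte genes alone with libraries left out, was chosen after the result was seen. For lists called with an estimated correlation in the splits no bound was written down, and the other tests of an explanation were written down before their results. Values of 1 library far from the other 3 of its group were found in 16 of 144 groups of values. The measure was the gap to the nearest value divided by the range of the group. About 1 in 20, or 7, would be found for independent values with a normal spread. CPM was not put on a log scale, however, and nearly all groups of values were of named genes, many of them region genes. The excess over 7 therefore cannot be weighed. In 13 of the 16 the outlying value was the highest. Most were region genes. Old 7 stood apart in Cnpy1 (26.6 CPM against 0.779 to 1.58, ratio 0.969), Slc6a5 (33.2 CPM against 1.34 to 3.36, ratio 0.937), Tfap2b (12.8 CPM, ratio 0.888) and Gfap (494 CPM against 325 to 343, ratio 0.893). Old_CP2 15 stood apart in Tph2 (49.6 CPM against 2.18 to 5.52, ratio 0.93), Slc6a4 (28.1 CPM, ratio 0.893), Cnpy1 (6.58 CPM, ratio 0.891) and, as the lowest, Serpina3n (25.4 CPM, ratio 0.878). Old_CP2 13 was highest in Hcrt (5.9 CPM against 0.0372 to 0.224, ratio 0.968) and Gal (2.46 CPM, ratio 0.866), and Old_CP2 11 in Pou4f2 (3.38 CPM against 1.2 to 1.5, ratio 0.865). The others were Young 3 in Cnpy1 (0.376 CPM, ratio 0.85) and in Pou4f2, whose single Young read gave a ratio of 1, Young 5 as the lowest in Gal (1.26 CPM, ratio 0.875), Old 10 as the lowest in Xist (981 CPM, ratio 0.963) and Old 8 in Ppargc1a (61.9 CPM, ratio 0.972).

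Between Old and Young the lists of striatum (12 of 15 genes fell), thalamus and habenula (8 of 16), hypothalamus and amygdala (4 of 16) and choroid plexus and ependyma (1 of 19) were called downward with the preset correlation but not with an estimated correlation (adjusted p = 0.107, 0.256, 0.347 and 0.362), while genes of midbrain and hindbrain neurons such as Pax7 (4.49) were among those that rose by most. A tissue block that held more midbrain and hindbrain in the old animals was tested with 16 genes of those regions not looked at before, 7 of which were at 1 CPM or more in Young. Their median log2 fold change was 0.934, above 100% of random lists, with 15 of 16 fold changes above 0 and 4 genes called (Chrna6, Evx2, Pitx3 and Pax8), and the most abundant, Aldh1a1 and Ddc, were at 91.4 and 23.3 CPM in Old and 58.3 and 12.2 in Young without a call (adjusted p = 0.17 and 0.124). This is consistent with a difference in the block taken, as a hypothesis. Age and strain acting on the same cells were not tested and stay open, since every old animal carries the other strain label. Between Old_CP2 and Old the same 16 genes had a median of 0.174, above 99.88% of random lists. Of these, 10 had fold changes above 0 and 0 were called. In both comparisons the median was below the spread of the 16 genes, which was 0.483 here and 1.18 between Old and Young. The spread thus does not set the comparisons apart. A difference in the block between treated and untreated mice thus stays open too. The random lists were matched on expression only, not on how far genes vary together, which limits this test in both comparisons.

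The erythrocyte list was higher in Old_CP2 than in Old, with 2 of 10 genes called. More residual whole blood was tested with 25 platelet, neutrophil and monocyte genes, whose median was -0.255 against 1.42 for the erythrocyte list, and the platelet and the neutrophil and monocyte genes alone had medians of -0.0736 and -0.736. The difference of 1.67 exceeds the summed spread of 1.33, the bound set beforehand for counting against more whole blood. The test cannot decide this, however. The most abundant genes, Nrgn at 526 CPM and Gp1bb at 100.4 CPM in Old, are platelet genes whose levels in brain would hide a small share of blood. Only 10 of the 25 genes were at 1 CPM or more in Old, and Pf4 (0.517 CPM) and Ngp (0.527 CPM) were among those below it. More whole blood thus stays open. In ratios of mean CPM the neutrophil and monocyte genes lay 2.16 below the erythrocyte list (summed spread 1.39), and 1.31 below it (summed spread 1.2) without Old 10, where their median was 0.0925, so their decrease rested on Old 10 but the gap did not. Erythroid cells of any kind, in place of haemoglobin made by brain cells, were tested with 11 other erythroid genes (median 0.0554, above 89.89% of random lists), 6 of them at 1 CPM or more in Old and led by Tmcc2 at 246 CPM, which left it open, as is an effect of CP2 on red blood cells or on brain cells, which was not tested.

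Several genes, among them Frem2, differed between all Old_CP2 and all Old libraries by a step. Linked genetic variants that differ between treated and untreated animals were first tested in the 100 genes of smallest p, which held 15 pairs of neighbours against a median of 20.5 and a highest of 130 in the other splits. The real split thus held no excess of such pairs. The other splits regroup the same libraries, and variants that differ among these would add pairs there too. The outcome therefore cannot count against variants. A second test was chosen after that outcome, because 100 genes are a wider set than the 10 called and could dilute them, and in it 3 of the 8 called loci lay on chromosome 3 and 15.2% of random draws had as many on 1 chromosome, which decides nothing. Other genes, chosen after their values were seen and not called (adjusted p = 0.0981 for both), had a pattern that variants could give: Gm6356 had 0 reads in every Old library, 255 to 353 in each Old_CP2 library, 1 in Young 1 and 221 to 326 in the other Young libraries, and Prss27 had 0 to 2 in Old, 22 to 110 in Old_CP2, 1 in Young 1 and 79 to 123 in the other Young. Variants thus stay open, as does CP2 acting on these genes, which was not tested.

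Among the 35 splits of 8 libraries, the real split called the most genes between Old and Young (1511, highest other 5). It also did between Old_CP2 and Young (1707, highest other 1). With 1 split as large, this passed the bound set beforehand. It is the smallest share that 35 splits can give, without adjustment over comparisons. The other splits also mix the groups, which adds to their spread. For Old_CP2 against Old chance was not excluded. There 3 splits called at least the 10 genes of the real split, and the highest other called 81. That split set Old 7, Old 9, Old_CP2 11 and Old_CP2 15, the 4 libraries lowest in choroid plexus transcripts, against the rest, which points to a structure of the samples. For the number of lists called with the preset correlation chance was not excluded in any comparison, with 12, 5 and 5 splits as large (real 19, 19 and 24, highest other 23, 22 and 25). With an estimated correlation the real splits called 2, 2 and 5 lists and no other split more than 1.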

How the results depend on the processing

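The tests with the choroid plexus covariate and without the 4 libraries lowest in choroid plexus transcripts were chosen after seeing the data. Of 76 results of named genes, 46 kept their direction and their side of the threshold under up to 16 alternatives, which include each library of the comparison left out, 25 lost their call in some, 5 gained one in some and 0 reversed. Other thresholds, limma voom with or without weights and the surrogate variable were not among these alternatives. The surrogate variable kept 307 of the 1511 calls between Old and Young. The cause of the changes below was not tested, except that other thresholds and fewer libraries act by construction. The choroid plexus covariate and the surrogate variable do so in part. The mean log2 CPM of the choroid plexus list was 3.88 to 4.49 in Young, above all libraries of Old (0.62 to 3.71) and Old_CP2 (0.67 to 3.45). The covariate thus overlaps with young against old and takes calls from both comparisons with Young. The surrogate variable was -0.395 to -0.07 in Young and 0.31 to 0.453 in the 4 libraries lowest in choroid plexus transcripts. In the other old libraries it was -0.226 to -0.052, so its overlap with young against old is partial.

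Genes called between Old and Young (1511) came to 2526 at an adjusted p under 0.1, 234 tested against a 1.2-fold change, 2474 with DESeq2, 343 with 1 surrogate variable, 247 with the choroid plexus covariate, 514 without the 4 libraries, and 855 (Young 4) to 1258 (Old 10) without single libraries. Between Old_CP2 and Old (10) they came to 23 at 0.1, 17 with no filter, 6 against 1.2-fold, 108 with DESeq2, 21 with voom weights, 21 without the 4 libraries, of which 5 were among the 10, and 6 (Old 9) to 38 (Old_CP2 15) without single libraries. Between Old_CP2 and Young (1707) they came to 2784 at 0.1, 380 against 1.2-fold, 2652 with DESeq2, 2682 with voom weights, 877 with 1 surrogate variable, 301 with the covariate, 709 without the 4 libraries, and 827 (Old_CP2 11) to 1590 (Old_CP2 15) without single libraries.

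The share of opposite sign (65.8%) was 74.1% without the 4 libraries, 45.2% with the Old libraries divided and 55.3 (Old_CP2 13) to 74.7% (Old 10) without single libraries. The covariance (-0.0442) was 0.00396 with the Old libraries divided and -0.0867 (Old 10) to -0.031 (Old_CP2 13) without single libraries. Pearson r across genes (-0.286) was 0.00835 with the Old libraries divided and -0.424 (Old 10) to -0.175 (Old_CP2 13) without single libraries. Simulated counts with no effect in any group gave -0.542 to -0.464. From the simulation that kept the difference between Old and Young no r was taken, so these values are not like for like. Sharing the Old libraries makes the covariance negative by construction.

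Lists called fell from 19, 19 and 24 to 2, 2 and 5 with an estimated correlation. In its directional form fry called 12 between Old and Young and 2 between Old_CP2 and Old, and in its mixed form 36 and 4. The direction of the list test reversed for choroid plexus (-0.0257) and ribosomal proteins (-0.0813) between Old and Young with the covariate, the former by construction. Between Old_CP2 and Old it reversed without the 4 libraries for complement and antigen presentation (-0.0449) and lymphocytes (0.163). Without Old 7 it reversed for glutamatergic neurons (-0.0141, up to 0.15 without Old 8) and synapse (0.00711, up to 0.0717 without Old 10). None of these lists between Old_CP2 and Old was called in the reversed direction (limma camera adjusted p 0.564 to 0.818). For lymphocytes and synapse only the direction of the test changed, and the median stayed positive.

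No paired analysis was possible because replicate numbers do not recur across groups. A sex covariate was not run, since Y-linked transcripts were near 0 in every library. With 4 libraries per group, edgeR found 59% of genes changed 1.5-fold on simulated counts, so some changes of that size would be missed.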

Other observations

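The tests of the ribosomal-like share, and those of the neutrophil, platelet and erythroid lists between Old and Young, with libraries left out, were chosen after the data were seen. Lists that were not called as a whole between Old and Young held genes that changed in both directions. Among 20 GABAergic neuron genes 3 rose and 5 fell, with the neuropeptide gene Npy at 22.6 CPM in Old and 35.6 in Young and the enzyme gene Gad1 at 402 and 338 CPM. Among 22 genes of hippocampal fields 4 rose and 2 fell, with C1ql2, a gene of mossy fibre synapses, at 31.1 and 14.2 CPM. Among 20 myelin genes 2 rose and 2 fell, with the alarmin Il33 higher by 0.76 and the tight junction gene Cldn11 at -0.50 on the log2 scale. Among 19 senescence genes 3 rose and 1 fell, with the cell cycle inhibitor Cdkn2a at 0.219 and 0.0278 CPM. Of 26 antioxidant genes 3 rose and 2 fell, with Sod2 at 184 and 157 CPM and Gpx1 at 40.7 and 53.8 CPM. Some of these lists were called without 1 library, which were antioxidants without Young 5 (adjusted p = 0.0238) or Old 9 (0.0457), myelin without Old 7 (0.016) and hippocampal fields without Old 7 (0.027).

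Neutrophil and monocyte genes had a median log2 fold change of 0.773 between Old and Young, and 6 of 13 were called higher (Csf3r, S100a9, S100a8, Ltf, Ngp and Lcn2), although Csf3r at 7.22 CPM was the most abundant in Old and 3 of the 13 were at 1 CPM or more in Young. The median was 0.774 without Old 10, but the calls other than Csf3r and Ngp ended without Old 10, Young 1, Young 4 or Young 5, and in Old the SD passed the mean for S100a9, S100a8 (0.878 ± 1.09 CPM), Ltf (0.604 ± 0.862 CPM) and Lcn2 (0.415 ± 0.417 CPM). Without Young 3 the calls of Csf3r, Ngp and S100a9 stayed, and without Old 7 or Old 8 all but that of Ltf. The platelet genes had a median of 0.0547, and the erythroid genes not looked at before one of 0.0399, with 1 called in each direction. The class II chain gene Cd74 was at 18.5 ± 16.8 CPM in Old_CP2 and up to 42.6 CPM in 1 library, against 7.57 ± 1.93 CPM in Old. The share of counts in Yam1 and AY036118, a pair of ribosomal-like loci, was 4.65% in Young, 5.65% in Old and 3.72% in Old_CP2. By two-sided exact permutation tests p was 0.286 for Old against Young, 0.0286 for Old_CP2 against Old, the smallest that 4 against 4 can give, and 0.143 for Old_CP2 against Young (Benjamini-Hochberg adjusted 0.286, 0.0858 and 0.214).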
